A study of Gossypium hirsutum with 2 samples.

How the data were processed

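Small RNA of ovules and of young leaves of cotton cultivar TM-1 was sequenced on an Illumina platform, per the labels, after RNA of 5 biological replicates had been mixed for each tissue. The deposited raw files list each distinct read sequence with its count, the number of reads that had that sequence, with no normalization by the authors. These reads were untrimmed, 34 nt long in ovule and 33 nt in leaf, and the 3' adapter was still present in them. The deposited processed files list the count of each distinct sequence after the authors had removed the adapter, and hold sequences of at least 15 nt with at least 3 copies, per the file headers and values. The trimming tool, an aligner and a genome build are not given in the sources used here. The raw ovule list summed to 5497711 reads, 102 fewer than its header states, and the raw leaf list to 3579841 reads. The headers of the processed files give totals after trimming of 4959151 reads in ovule and 1643140 in leaf, while the listed sequences hold 333771 and 484896 reads.

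The processed lists were not used for the main results. They hold trimmed sequences of 15 to 24 nt in ovule and 15 to 23 nt in leaf, plus full-length entries of 34 nt and 33 nt, so the adapter had apparently been removed only where at least 10 nt of it had been read. The raw reads were therefore trimmed here. The adapter TCGTATGCCGTCTTCTGCTTG was searched at each position, needing at least 7 nt with mismatches at no more than 20% of the overlap, and the position with the best overlap minus 3 per mismatch was taken. Inserts of 15 to 26 nt were kept. Inserts that resembled the 3' adapter (at most 4 mismatches in the first 15 nt) or held the end of the 5' adapter, AGTCCGACGATC (at most 1 mismatch), were removed. This rule was set after the raw reads had been seen. It left 3424919 ovule reads (62.3% of raw) in 3033902 distinct sequences and 971655 leaf reads (27.1%) in 641077 distinct sequences. Of the raw reads, 5.91% in ovule and 51.0% in leaf had an insert under 15 nt, and 31.3% and 19.2% had no adapter found. Mismatches in the first 9 nt of the adapter behind inserts of 21 to 24 nt came to 4.70% per base in ovule and 2.73% in leaf, and at G bases to 10.9% and 7.33%. Only reads that passed the adapter match were counted, so these rates are lower limits. Behind 24-nt inserts the ovule reads held 1 adapter base more and were allowed more mismatches than the leaf reads. The rates of the libraries are thus not strictly comparable.

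Reads were assigned to 35 families by 46 reference sequences of plant miRNAs and tasiARF, written from textbook knowledge because no miRNA database was used here, so cotton variants of a family can lie at a mismatch. A sequence of 19 to 24 nt was assigned where its 5' end lay within 2 nt and its 3' end within 3 nt of a reference, with an overlap of at least 18 nt and at most 2 mismatches. It went to the family with the fewest mismatches, and ties between families were left out. Shuffled reference sequences, averaged over 5 sets, took 1.20 reads in ovule and 0.400 reads in leaf. Levels are RPM of trimmed reads. All reads of the file had been set as the denominator, on the assumption of a list of trimmed tags; because the raw lists were untrimmed and held many adapter reads, the trimmed reads were used in their place.

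With 1 library per tissue no test was run. A family was called measured at 50 or more reads in the higher library and called higher at a ratio of at least 2-fold. Ratio intervals are exact (Clopper-Pearson) conditional binomial intervals, and intervals of shares are Wilson intervals, both at 95%. A library without a read of a sequence was set to a floor of 3 counts. A library with any read kept its count, even below that floor. A sequence with few reads in 1 library can therefore rank above a sequence with none there. PCR copies cannot be told from independent molecules, so intervals and floors cover counting error only. The reference sequences, the matching rule, the 50-read and 2-fold limits, the lists and the first set of alternatives were chosen before the data were examined. The naming rule, also set then, took the 10 most abundant families of each library, the 10 largest ratios in each direction among measured families, as far as there were that many, and the measured members of each list. It also took, in each direction, the 5 sequences of 20 to 24 nt outside the families with the largest ratio at 100 or more RPM. Lists with at least 3 measured families were described by their median log2 ratio and its percentile among 10000 random lists of measured families of the same size matched on abundance.

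Fragments of rRNA, tRNA, adapter and animal miRNAs were counted with at most 2 mismatches in trimmed reads and 3 in reads without adapter. The rRNA references, 5.8S and 5S only, took 628 RPM in ovule and 1669 RPM in leaf, and the nuclear-type tRNA references 75.3 and 1043 RPM. The larger rRNAs were not among the references, so the rRNA levels are lower limits. The animal miRNAs took 9 reads in ovule and 3 in leaf, and the TruSeq small RNA adapter 0 reads in both, which allows up to 3 counts. A list of 5 plastid tRNAs was added after abundant leaf reads had been seen. The alternatives of that set changed the scaling, the mismatches, the read minimum, the depth and the file. The added ones changed the denominator, the adapter rule, the ovule read length and the sequence list. The pipeline was tested on simulated reads with errors, in which 35 of 35 families came within 0.25 log2 of the true ratio after centring, and 94.7% of ovule and 99.2% of leaf family reads were found. The simulated family reads all started from a listed sequence, with errors rarer than those measured in the adapter. The test therefore does not cover families whose main form lies at mismatches from the list, such as miR172 and miR3954. No genome was used here, so no positions are given. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.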

Results

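Small RNA was sequenced from 2 tissues of upland cotton (Gossypium hirsutum), cultivar TM-1, a standard genetic line of the species. The ovule library came from ovules taken from -1 to 1 day post anthesis, the time at which fibre cells begin to grow out of the ovule surface. The leaf library came from young leaves that grew close to those ovules. RNA of 5 biological replicates was mixed for each tissue before sequencing, so each tissue had 1 library and the differences between tissues had no replicate check. No p-value is given, and all intervals are 95% intervals that cover counting error only. The ovule library held 5497711 reads of 34 nt and the leaf library 3579841 reads of 33 nt. After adapter removal 3424919 ovule reads and 971655 leaf reads of 15 to 26 nt were left, and levels are given as RPM of these trimmed reads. Reads of 3' adapter alone made up 4.70% of the raw ovule reads and 49.6% of the raw leaf reads. A count of 3 reads corresponded to 0.876 RPM in ovule and 3.09 RPM in leaf, the upper limit for a sequence without a read. The study concerned miRNAs of ovule and fibre development, and the question put to these libraries was which small RNAs differed between ovule and leaf.

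The ovule library was dominated by 24-nt RNAs, the size of the siRNAs that direct DNA methylation in plants. The leaf library was divided between 24-nt RNAs and 21-nt RNAs, the size of most plant miRNAs. The 24-nt class held 63.7% of ovule reads (Wilson interval 63.6% to 63.7%) and 36.8% of leaf reads (36.7% to 36.9%). The 21-nt class held 8.77% of ovule reads (8.74% to 8.80%) and 31.5% of leaf reads (31.4% to 31.6%). Reads of 22 nt made up 7.69% of the ovule library and 13.6% of the leaf library, and reads of 23 nt 13.1% and 10.4%. The 24-nt class was highly diverse in both tissues, with 91.6 distinct sequences per 100 reads in ovule and 91.7 in leaf. The 21-nt class held 66.1 distinct sequences per 100 reads in ovule and 32.7 in leaf, counts that include read errors, which were more frequent in ovule (4.70% of adapter bases against 2.73%). Among sequences read at least 2 times, the 24-nt share was 51.5% in ovule and 11.6% in leaf. Being read again depends on depth, and the ovule library was deeper, so the size of this gap is not comparable. No adapter was found in 31.3% of raw ovule reads and 19.2% of raw leaf reads, and the lengths of those inserts were not measured.

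**Figure D1:**
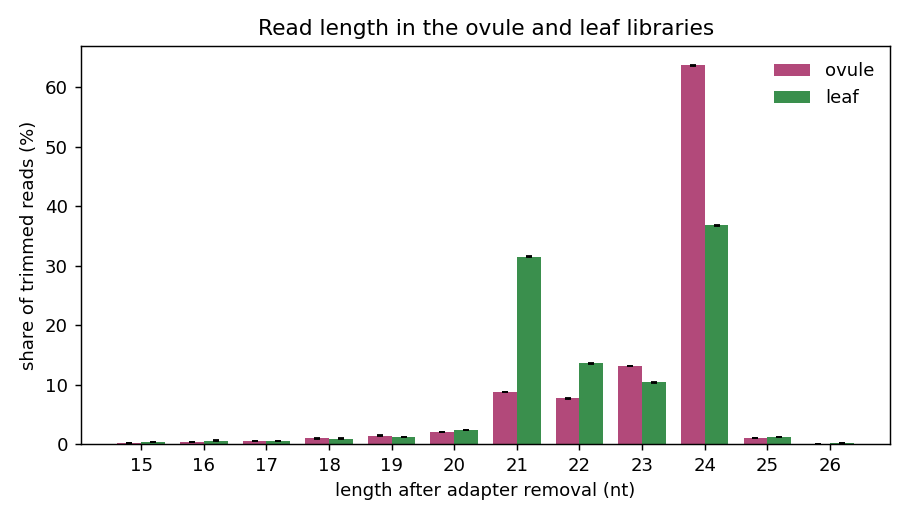
Share of trimmed reads (vertical axis, percent) at each length after adapter removal (horizontal axis, nt) in the ovule and leaf libraries, with black bars for the 95% Wilson interval. The 24-nt bar reaches 63.7% in ovule and 36.8% in leaf, and the 21-nt bar 8.77% and 31.5%.

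Together the listed miRNA families and tasiARF took a far larger part of leaf than of ovule reads, largely through miR156/miR157 and miR3954. The 35 listed families took 21.2% of leaf reads (21.1% to 21.3%) and 2.52% of ovule reads (2.501% to 2.534%), a share 8.41-fold higher in leaf. The size of this gap depended on the counting, with 5.75% against 1.57% of all raw reads and 12.2% against 0.693% for sequences identical to a listed one. In leaf, miR156/miR157, which represses SPL transcription factors and maintains the juvenile phase, accounted for 73.0% of the listed reads and 15.5% of all trimmed reads. miR3954, a miRNA known from few plant lineages, accounted for a further 16.3% of the listed leaf reads. Nearly all of these were at 2 mismatches from the listed sequence, since 844 of its 33540 leaf reads had no more than 1 mismatch. These 2 families held most of the listed leaf reads, so the gap in share does not describe the other families. In ovule, miR165/miR166, which represses the HD-ZIP III factors of organ polarity, accounted for 54.7% of the listed reads and 1.38% of all trimmed reads.

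Of the 35 families, 20 had at least 50 reads in the library where they were higher, and these are called measured. Among the measured families 12 were at least 2-fold higher in leaf, 4 were at least 2-fold higher in ovule and 4 lay within 2-fold. Their median log2 ratio of ovule over leaf was -2.85, a level 7.22-fold lower in ovule, so the families are also given relative to that general difference. Dividing by the reads of listed families moved each log2 ratio up by 3.07 and gave 8 families higher in ovule and 7 higher in leaf. Most listed leaf reads were miR156/miR157 (73.0%), so this shift mainly reflected that family. Centring on the median family also gave 8 and 7, and dividing by all raw reads gave 7 and 11. A scaling moves all families by the same amount, here almost only upward, so it could turn only families that were lower in ovule. Of these, 10 stayed lower in ovule under each scaling, while miR390, miR3476 and miR159 turned. Reads that began with U were rarer in ovule also outside the listed families, at 25.8% against 48.6% of 21-nt reads. The ratios were not corrected for first base, so a library difference by first base bears on those near 2-fold. Of the families higher in ovule, miR172 and miR2949 begin with A, while miR167 and miR858 begin with U.

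**Figure D2:**
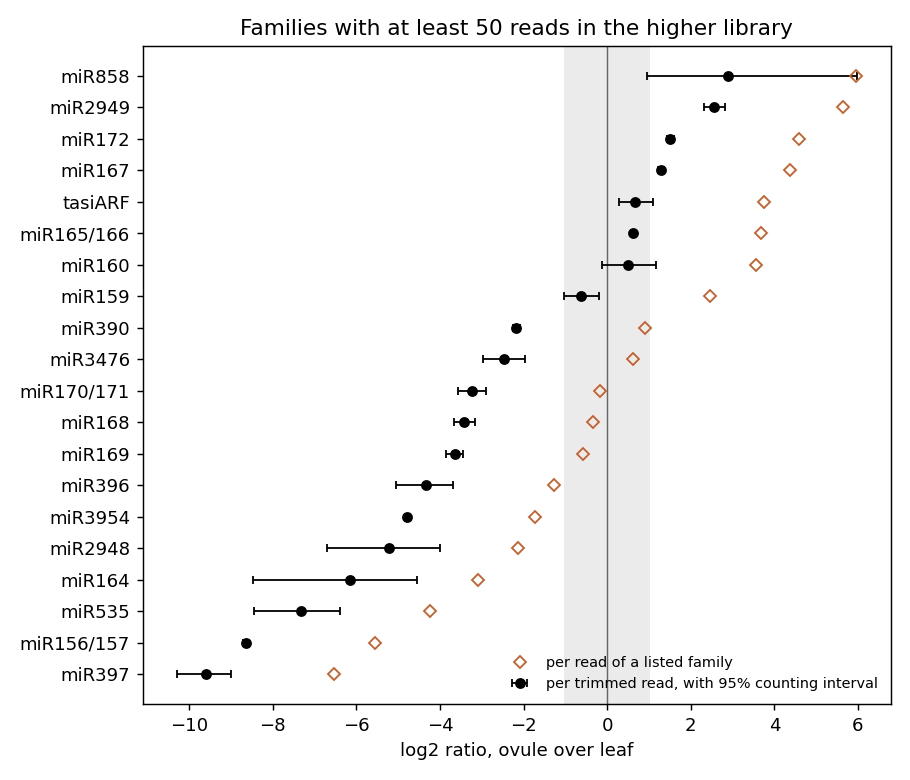
Log2 ratio of ovule over leaf (horizontal axis) for the 20 measured families. Black points are levels per trimmed read with 95% exact counting intervals, open diamonds are levels per read of a listed family, and the grey band marks less than 2-fold; ratios run from -9.61 for miR397 to 2.88 for miR858, and miR3476, miR390 and miR159 cross 0 between the scalings.

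The laccase family miR397 and the phase families miR156/miR157 and miR535 showed the widest gap in favour of leaf. miR397, which represses laccases of lignin formation, had 4787 RPM in leaf and 6.13 RPM in ovule, a level 781-fold higher in leaf (510 to 1262). miR156/miR157 had 154564 RPM in leaf and 388 RPM in ovule, a level 398-fold higher in leaf (377 to 421). miR535, whose sequence resembles miR156, was 160-fold higher in leaf (83.3 to 352), from 408 leaf reads and 9 ovule reads. These 3 families were lower in ovule under every scaling, with log2 ratios per listed read of -6.54, -5.57 and -4.25. Without mismatches the log2 ratio of miR535 was -5.91, from 1 ovule read and 17 leaf reads. The miR157 sequence TTGACAGAAGATAGAGAGCAC made up 72.0% of the family's leaf reads and 40.6% of its ovule reads. For miR397 the form TCATTGAGTGCAGCGTTGATG had 1366 reads in leaf and 0 in ovule, with a log2 ratio of -10.65 against the floor of 3 counts and an upper limit of -10.35 by its counting interval. The form ATTGAGTGCAGCGTTGATGAA had 2071 leaf reads and 4 ovule reads.

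A further 7 families, among them 3 of organ patterning, were higher in leaf. miR164, which represses NAC factors of organ boundaries, was 71.7-fold higher in leaf (23.4 to 357), with 61 leaf reads and 3 ovule reads. miR396, which represses growth-regulating factors, was 20.2-fold higher (12.9 to 33.02), and miR170/miR171, which represses the HAM factors of meristems, was 9.45-fold higher (7.51 to 12.0). miR168, which represses the silencing protein AGO1, was 10.7-fold higher in leaf (8.96 to 12.8). miR169, which represses NF-YA factors, was 12.6-fold higher (10.9 to 14.6). Among the families of cotton or few lineages, miR3954 was 27.8-fold higher in leaf (26.9 to 28.7) and miR2948 37.0-fold higher (16.1 to 105). All 7 families were lower in ovule under each scaling, although per listed read miR169 had a log2 ratio of -0.58, miR168 of -0.34 and miR170/miR171 of -0.17, all within 2-fold. Without mismatches miR169 had a log2 ratio of -1.72, from 142 ovule and 133 leaf reads, and miR170/miR171 of -0.82, within 2-fold and from 2 ovule reads and 1 leaf read. The miR3954 reads were mainly the form TTGGACAGAGTAATCACGGTCG, with 30960 leaf reads and 3552 ovule reads. At no more than 1 mismatch its log2 ratio was -4.15, from 167 ovule and 844 leaf reads. Without mismatches 0 ovule reads and 3 leaf reads of miR3954 were left. With each family's most frequent sequence added to the list its log2 ratio was -4.57.

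Within miR169 the sequence forms differed in direction. The form CAGCCAAGGATGATTTGCCGG had 351 leaf reads and 2 ovule reads, a log2 ratio of -9.27 (-12.32 to -7.41). The form CAGCCAAGGATGACTTGCCGA had 73 ovule reads and 9 leaf reads, a log2 ratio of 1.20 (0.20 to 2.39).

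miR390 and miR3476 were higher in leaf per trimmed read but not relative to the other families. miR390, which starts the formation of tasiARF, was 4.51-fold higher in leaf (4.26 to 4.77), while its log2 ratio was 0.90 per listed read and 0.68 after centring on the median family. The cotton family miR3476 was 5.51-fold higher in leaf (3.88 to 7.88), with 0.61 per listed read and 0.39 after centring.

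The families higher in ovule were miR858, miR2949, miR172 and miR167. miR858, which represses MYB factors, had 15.2 RPM in ovule and 2.06 RPM in leaf, a level 7.38-fold higher in ovule (1.94 to 62.5) that rested on 52 ovule reads and 2 leaf reads. miR2949, a cotton family, was 5.90-fold higher in ovule (4.99 to 7.03), with 868 RPM against 147 RPM. miR172, which represses AP2-like factors and acts opposite to miR156 in phase change, was 2.86-fold higher in ovule (2.69 to 3.04). miR167, which represses the auxin response factors ARF6 and ARF8, was 2.46-fold higher (2.34 to 2.58), with 4380 RPM against 1783 RPM. With a stricter match to the listed sequences, the log2 ratio at no more than 1 mismatch was -0.39 for miR172 and 0.35 for miR858, the latter within 2-fold and from 9 ovule reads and 2 leaf reads. The log2 ratio without mismatches was -3.15 for miR172, -2.01 for miR167 and -0.82 for miR858, the last from 3 reads in all. With each family's most frequent sequence added to the list it was 1.96 for miR172, from 16092 ovule and 1174 leaf reads. It was then 1.37 for miR167 and 2.73 for miR858.

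The miR172 reads of ovule and leaf were different sequence forms. The form AGAATCCTGATGATGCTGCAG made up 62.3% of the miR172 reads in ovule and 0.512% in leaf, with 7363 reads against 6. The form AGAATCTTGATGATGCTGCAT, identical to the listed sequence, made up 69.9% in leaf and 2.38% in ovule, with 820 reads against 281. The ovule form had a log2 ratio of ovule over leaf of 8.44 (7.32 to 9.89), and the leaf form had a log2 ratio of -3.36 (-3.56 to -3.17).

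**Figure D3:**
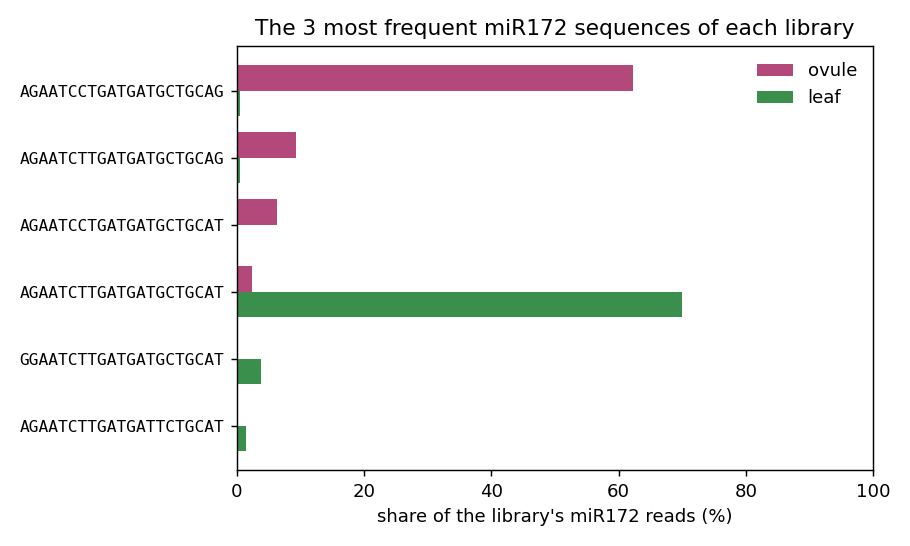
Share of each library's miR172 reads (horizontal axis, percent) taken by the 3 most frequent sequence forms of each library, 6 forms in all. The form AGAATCCTGATGATGCTGCAG takes 62.3% in ovule and 0.512% in leaf, and the form AGAATCTTGATGATGCTGCAT 2.38% in ovule and 69.9% in leaf.

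miR165/miR166, tasiARF, miR160 and miR159 lay within 2-fold per trimmed read. miR165/miR166 was the most abundant family in ovule at 13776 RPM, against 9029 RPM in leaf, and was 1.53-fold higher in ovule (1.49 to 1.56). tasiARF, the siRNA that represses ARF2, ARF3 and ARF4, was 1.60-fold higher in ovule (1.21 to 2.14). miR160, which represses ARF10, ARF16 and ARF17, had a log2 ratio of 0.49 with an interval that included 0 (-0.12 to 1.16). Per listed read the log2 ratios of miR165/miR166, tasiARF and miR160 were 3.68, 3.75 and 3.57. tasiARF had a log2 ratio of -0.43 per trimmed read when only identical sequences were counted. miR159, which represses GAMYB-like factors, had a log2 ratio of -0.62 per trimmed read (-1.04 to -0.19) and of 2.45 per listed read.

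By list, phase change had the lowest median, although its members differed in direction. Of its 3 measured members miR156/miR157 and miR535 were higher in leaf and miR172 was higher in ovule, with a median log2 ratio of -7.32. That median lay at percentile 1.98 of 10000 random lists of measured families matched on abundance, a description of these libraries only. The median is the value of miR535 alone, from 9 ovule reads. The random lists were drawn from the same 20 measured families, so the percentile restates how extreme the members are. The auxin list had 4 measured members, with miR167 higher in ovule, miR390 higher in leaf and miR160 and tasiARF within 2-fold, and its median of 0.58 lay at percentile 87.7. Organ patterning had 4 measured members, with miR164, miR170/miR171 and miR396 higher in leaf and miR165/miR166 within 2-fold, and its median of -3.79 lay at percentile 35.0. The list of cotton or few lineages had 4 measured members, with miR2948, miR3476 and miR3954 higher in leaf and miR2949 higher in ovule, and its median of -3.63 lay at percentile 27.5. Per listed read the 4 medians were -4.25, 3.66, -0.72 and -0.56, and without mismatches the auxin median was -0.83. The remaining lists had fewer than 3 measured members. Both measured nutrient families, miR169 and miR397, and the sole measured family of the small RNA machinery, miR168, were higher in leaf. In the MYB list miR858 was higher in ovule and miR159 lay within 2-fold. No family of the NBS-LRR list or of the unsorted remainder reached 50 reads.

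Abundant sequences outside the listed families also separated the tissues. In ovule the sequence ATGTTAAGATTTGTAAGGTTT had 508 reads and leaf had 0, so it was at least 48.0-fold higher in ovule against the floor of 3 counts and at least 38.9-fold by its counting interval. TTTGTACTTTAGATGTCTCTC was 22.9-fold higher in ovule (11.5 to 53.2) and TTACTTTAGATGTCTCCTTCA 15.5-fold higher (8.82 to 30.2). The 24-nt sequence ATCTTGTGTTTGGTTGAATGGAAT was 18.3-fold higher in ovule (8.80 to 45.7), and AGTGGTTGGGCATTGTTCTAC 10.4-fold higher (6.03 to 19.7). In leaf TTGACAGAAGATATATACCAC was 2781-fold higher (769 to 22984), from 2 ovule reads. TTGACAGAAGATATATACTAC was 881-fold higher (156.7 to 34943) and TTGACAGAAGATATCTACCAC 476-fold higher (84.0 to 18933), each from 1 ovule read. Those 3 sequences lay 3 or 4 mismatches from miR156/miR157, beyond the limit of 2 for a match. Adapter G bases were misread at 7.33% in leaf, with 41.4% of these errors read as T. The 3 sequences may be misread copies of miR156/miR157, itself far higher in leaf, which was not tested. The first had 1578 leaf reads and differs at 3 G bases from the main miR157 sequence, which had 108125. Forms with 1 of these G bases read as T had 3488 and 3780 leaf reads. Independent misreads would make changes at 3 bases far rarer than at 1. The adapter rates alone therefore do not account for the count of the first sequence. The sequence TACCTGGTTGATCCTGCCAGTAG, the start of 18S rRNA, was 478-fold higher in leaf (231 to 1192), and GGTAGTTCGACCGCGAAATT 1227-fold higher (219 to 48587).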

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

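The signals in this part were found in reads outside the comparisons between tissues, and the tRNA list was written after the abundant leaf reads had been seen, from general knowledge and unchecked against a cotton plastid genome. No control library existed, so the sole bar was the limit for a count of 0, 3 counts, which says nothing of their weight. Reads that consisted of 3' adapter alone made up 4.70% of raw reads in ovule and 49.6% in leaf. Inserts that held the end of the 5' adapter made up 0.202% of raw ovule reads and 0.624% of raw leaf reads. Among reads in which no adapter was found, reads matching the 5 listed plastid tRNAs made up 17.3% in leaf (17.2% to 17.4%) and 0.00547% in ovule (0.00447% to 0.00669%). The sequence listed as plastid tRNA-Asp alone took 111223 of these reads in leaf and 93 in ovule. In the trimmed reads of 18 to 26 nt the same 5 tRNAs took 129 RPM in leaf and 6.42 RPM in ovule. No explanation of these signals was tested.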

How the results depend on the processing

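The alternatives by adapter mismatch, ovule read length, raw reads, the authors' totals, untrimmed reads, removal of listed families and the extended list were chosen after the data were seen, and the others were planned. All reads of the file had been the planned main denominator. They became an alternative when the trimmed reads replaced them, after the raw reads had been seen. No replicate could be left out with 1 library per tissue, and the cause of a change was not tested unless it is given. The 24-nt share stayed higher in ovule in the trimmed reads. It was 65.8% in ovule and 51.1% in leaf over distinct sequences and 51.5% and 11.6% over sequences with at least 2 reads. The latter shares also depend on depth, which was greater in ovule. The processed lists gave 38.8% and 0.0% and decide nothing, since the leaf list could hold no trimmed 24-nt sequence. Without adapter mismatches it was 66.4% and 39.1%, without listed families 65.3% and 46.7%, and with ovule reads cut to 33 nt 61.0% in ovule.

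The number of families higher in ovule, 4 in the report, was 8 by listed reads, 8 by median of ratios, 7 by all raw reads, 2 with at most 1 mismatch, 1 with an exact overlap and 1 with identical tags. The number higher in leaf, 12 in the report, was 7 by listed reads and 7 by median of ratios. It was 21 with at least 10 reads, 22 with no minimum and 6 with at least 500 reads, as more or fewer families entered.

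The share of listed families stayed higher in leaf throughout. With at most 1 mismatch it was 1.72% in ovule and 16.1% in leaf, with an exact overlap 0.795% and 12.8%, with identical tags 0.693% and 12.2%, and with the extended list 2.75% and 22.2%. It was 2.55% and 21.5% of reads of 18 to 26 nt, 1.62% and 11.9% in the processed files, 1.57% and 5.75% of all raw reads, and 1.68% and 12.4% of trimmed and untrimmed reads.

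The medians of phase change, auxin, organ patterning and cotton or few lineages were -4.47, 3.44, -0.94 and -0.78 by median of ratios and -4.25, 3.66, -0.72 and -0.56 by listed reads. With an exact overlap they were -5.91, -0.83, -2.74 and -2.26. Of these, the phase change, organ patterning and cotton medians rested on families with few reads. These were miR535 (1 ovule and 17 leaf reads), miR170/miR171 (2 and 1) and miR3954 (0 and 3). Of 278 values of single families under alternatives, 112 left the counting interval with no change of a called direction, 10 in 5 families turned, and the others stayed within the interval. miR3476 was 0.61 by listed reads and 0.39 by median of ratios, and miR390 0.90 and 0.68. miR172 was -0.39 with at most 1 mismatch, -3.15 with an exact overlap and -3.36 with identical tags, since its main ovule form lies 2 mismatches from the listed sequence. With the extended list, which takes in that form, miR172 was 1.96. miR167 was -2.01 with an exact overlap (240 ovule and 274 leaf reads) and -0.95 with identical tags, and miR858 -0.82 with an exact overlap (2 reads and 1). miR3954 and miR858 had no identical tag and gave no value there. Depth limited miR858, miR164 and miR2948 most among measured families, with 2 leaf reads, 3 ovule reads and 6 ovule reads.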

Other observations

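The first base of the small RNAs differed between the libraries. Among 24-nt reads 67.8% began with A in ovule and 52.0% in leaf, the base found on most siRNAs bound by AGO4-type proteins. Among 21-nt reads 38.2% began with U in ovule and 73.8% in leaf, and without the listed families 25.8% and 48.6%. Reads that began with G were rarer in ovule at each length from 20 to 24 nt, for example 3.84% against 15.8% at 24 nt. Those with U were also rarer and those with A or C more frequent at each of these lengths, with or without the listed families. The shift was thus not particular to a size class. A difference in library preparation or sequencing could not be separated from a tissue difference. Of all leaf sequences 5.36% were also read in ovule at 24 nt, 4.67% at 21 nt and 9.91% at 22 nt, and of those with at least 3 leaf reads 46.7%, 28.0% and 58.5%. At equal reads per class the 21-nt class held 2.02 times as many distinct sequences in ovule as in leaf, the 22-nt class 1.63 times and the 24-nt class 1.05 times. These ratios include read errors, and bases of recognised adapters were misread more often in ovule (4.70%) than in leaf (2.73%). The 21-nt ratio also reflects the main miR157 sequence, which held 108125 of the 306096 leaf reads of that length. It is therefore not a measure of diversity apart from that sequence. The sequence AGTTACTAATTCATGATCTGGCAT, picked after its values were seen, had 6696 reads in leaf and 79 in ovule and was 299-fold higher in leaf (239 to 378).

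The tests that follow were chosen after the result was seen, although the ratio per listed read and that of identical tags had been set as alternatives beforehand. The 24-nt share was 63.7% in ovule and 36.8% in leaf. The extra base of the ovule reads did not account for the whole gap, since ovule reads cut to 33 nt gave 61.0%. The many miRNA reads of leaf accounted for a part of it, as the shares were 65.3% and 46.7% without the listed families, still 18.6 points apart. The loss of reads without adapter cannot be told apart from a tissue difference: if no lost ovule read and every lost leaf read had held 24 nt, the difference would be -20.6 points. That bound is wider than the reads allow, since 17.3% of the lost leaf reads matched plastid tRNAs over their whole length. It was not recomputed without them, and most lost leaf reads were not identified. A difference between ovule and leaf in 24-nt siRNAs stays open, as does a difference in library preparation, which could not be separated with 1 library each.

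The authors' leaf list holds no sequence of 24 nt, although 36.8% of the trimmed leaf reads had that length here. Of the 33-nt entries of that list 31.0% ended in the first 9 nt of the adapter behind 24 nt of insert, and these held 11.4% of the reads of the 33-nt entries. The missing class is consistent with a trimming rule that needed at least 10 nt of adapter, which a 33-nt read of a 24-nt RNA cannot hold. No biological explanation was tested.

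miR156/miR157 was 398-fold higher in leaf. Reads closest to the 20-nt miR156 sequence had a log2 ratio of -8.92 (-9.66 to -8.28), from 19 ovule and 2618 leaf reads. They were a small part of the family's 1329 ovule and 150183 leaf reads. Misread copies of the main miR157 sequence would carry a like ratio, so these reads cannot decide on over-amplification of 1 sequence in leaf. A lower yield of all listed families in ovule was argued against by the log2 ratio of -5.57 per listed read. Of the family's reads 46.8% in ovule and 74.4% in leaf had no mismatch, so errors lowered the ovule count more. The log2 ratio was -9.47 for identical tags and -8.64 with 2 mismatches allowed, a shift of 0.84 in the direction of such errors. That shift is a small part of the ratio. Reads with more than 2 mismatches are missing from both ratios, so the full effect of errors was not measured. A candidate explanation is a true difference in miR156/miR157 between ovule and young leaf, as a hypothesis from the data it was tested on. Over-amplification of 1 sequence in leaf stays open, and a difference in library preparation stays untested.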
